A study of Mus musculus with 48 samples.

How the data were processed

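Liver RNA of wild-type and PPARα-null mice was measured on 48 Agilent mouse expression arrays in a single colour, Cy3. The labels give 12 groups: each genotype received a liquid diet with 4% ethanol or an isocaloric control diet with maltose dextran, and was sampled at 1M, 2M and 4M. The unit behind M is not spelled out, and on every sample the entries of the treatment and time fields are exchanged, so that groups were read from the titles together with these fields. Each group holds 4 arrays, apart from the PPARα-null 1M groups with 5 control and 3 alcohol arrays.

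Per the file headers, the authors quantified each array with Feature Extraction 10.7.3.1, and the deposited processed signal is a spot intensity after the background treatment of that software, taken here as not scaled between arrays. The 4M arrays were extracted with a protocol that marks no non-uniform spots, and the 1M and 2M arrays with a protocol that does. Per the labels' protocols, total RNA was extracted with Trizol and a column kit and labelled as cDNA. A table of log2 values of the same arrays was also deposited by the authors. Set against the scanner values, this table ran in the same direction on every array and was centred on each probe's median over the 48 arrays, while its scaling between arrays stayed unknown. Its column medians, in replicate order, were 0.030, 0.030, 0.076 and 0.022 for wild-type control 1M, 0.048, 0.033, 0.092 and 0.032 for wild-type alcohol 1M, and 0.022, -0.109, -0.095, -0.112 and 0.017 for null control 1M. They were -0.111, -0.126 and -0.103 for null alcohol 1M, -0.0068, -0.105, 0.0065 and -0.014 for wild-type control 2M, and -0.0032, -0.0029, 0.020 and 0.086 for wild-type alcohol 2M. For null control 2M they were -0.013, -0.015, -0.015 and -0.012, for null alcohol 2M -0.051, -0.012, 0.096 and 0.154, and for wild-type control 4M 0.090, 0.077, 0.065 and -0.026. The remaining medians were 0.059, 0.023, 0.0058 and 0.038 for wild-type alcohol 4M, -0.042, -0.102, -0.043 and 0.0022 for null control 4M, and -0.0075, -0.0063, -0.043 and -0.049 for null alcohol 4M. This table served as an alternative.

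Control spots and spots marked as non-uniform or population outliers were left out, and saturation occurred on 0 spots. The processed intensity of each array was divided by its 75th percentile and taken to log2, and spots of a probe were averaged. The files used here carry no gene name column, so accessions were matched, without versions, to RefSeq names of assembly GRCm38.p6, used for names only: 26762 of 55681 probes matched, giving 20284 symbols, and 28919 probes kept the accession or name in the file. Of 26430 messenger RNA accessions, 25934 matched. A gene was represented by its probe with the highest mean over all arrays, which gave 37147 genes. A gene was tested if that probe was well above background on at least 3 arrays of a group, which 34518 genes passed, 18928 of them with a symbol. Of their values 4.17% were missing because of left-out spots, and 45.8% of genes had no missing array.

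Differences were tested with limma 3.58.1 in R 4.3.3 (packages statmod 1.5.0, jsonlite 2.0.0 and, for reading, version 1.17.8 of data.table), with 12 group means fitted to all 48 arrays, a moderated variance per gene (36 residual and 3.56 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. All tests were two-sided. The group-means fit was computed in closed form around missing spots, with limma's variance moderation, and gave limma's own t statistics on genes without missing arrays. The main comparisons were alcohol against control in each genotype, averaged over the 3 times, the difference between these responses, and PPARα-null against wild type on the control diet. Each time was also tested alone, and a moderated F test asked whether a response differed between times. Of 37 gene lists on lipid, bile acid, alcohol, xenobiotic and stress pathways, inflammation, fibrosis, sex-biased expression and liver or other cell types, those with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with the other genes. The fry p tests whether members move in 1 direction on balance, its mixed p whether they change in either direction, and neither compares them with other genes. Counts of list members are given over all genes and adjusted over the list alone. A fold from a group in which no array was well above background was computed as a bound, against the higher of the probe's signal and the lowest signal well above background on each array.

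Groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Ppara; Cyp7a1, Cyp4a14, Cyp4a10, Fgf21, Cyp2e1, Srebf1, Cyp2b10, Tnf, Col1a1, Cdkn1a, Xist and Ddx3y whatever their p; from each list up to 2 members per direction with the smallest adjusted p; the 10 largest changes per direction of the same sign at all times; and at each time the 3 largest changes per direction, skipping names that are clones or accessions. A few genes that the rule names are not reported here, without replacement, while all counts and list tests include them. From the remaining 182 genes, a smaller number is described. Genes whose call was lost when a single array was left out were mostly passed over, and so were the largest genotype differences outside the lists; both choices were made after the values were seen.

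Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the authors' table, other filters on dim genes, the mean of a gene's probes, fits on the compared groups alone, the replicate number as a block, the row on the slide as a covariate, a variance trend with robust estimation, array weights, a minimum log2 change of 1, and each array or time left out. Because the files used here hold no mean signal column, normexp used median signals. For the genotype difference, the slide was fitted as a random block and slide means were compared. Neither of these fits held the time, so differences between times, scan days and extraction protocols counted there as differences between slides. Spots marked non-uniform kept, a fit without 3 arrays of outlying shares of probes above background, and a genotype difference relative to the median of all genes were added after seeing the data. So were an exact two-sided permutation test of list medians between slides and the exchange of genotypes between whole slides of a time.

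The procedure was tested on simulated data of 34518 genes, 100 of them changed by log2 1 and another 100 by log2 2. For alcohol in wild type, 63 and 93 of 100 were recovered with 6 false calls. For alcohol in PPARα-null it recovered 63 and 87 of 100 with 4 false calls, for the difference of responses 32 and 75 with 7, and for genotype 67 and 94 with 8. At a single time it was 19 and 70 in wild type at 1M, 21 and 70 at 2M, and 19 and 75 at 4M. In PPARα-null it was 14 and 63 at 1M, 15 and 60 at 2M, and 17 and 73 at 4M. A list of 30 genes shifted by log2 0.5 in the wild-type alcohol comparison (34277 genes) was called, with 0 of 30 unshifted lists called by limma's camera. The simulated noise was independent between arrays and between genes, without effects of slide, row or array. These false calls therefore check the computation and do not give the rate of false calls in the real data. The number of arrays limits precision. Nothing in the labels says that arrays of a group came from separate animals, so p-values measure the spread between these samples.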

Results

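Gene expression was measured in the livers of wild-type mice and of mice lacking PPARα, the nuclear receptor that drives fatty acid oxidation genes, after an alcohol or an isocaloric control diet. Each of the 48 arrays carried 59305 spots, and 34518 genes were tested. All groups held 4 arrays, except null control 1M with 5 and null alcohol 1M with 3. The 75th percentile of the processed intensity ran from 264 to 3305 per array. On the control diet at 1M it was 1090 to 1505 in wild type and 1616 to 2172 in null. At 4M it was 264 to 368 and 1014 to 1488, and at 2M the ranges overlapped (1083 to 3305 and 1697 to 2428). Intensity before scaling thus separated the genotypes at 1M and 4M. The share of spots well above background was lowest on null control 4M replicate 4 (45.3%) and wild-type control 4M replicate 4 (57.3%), and highest on wild-type control 2M replicate 2 (97.2%). Each of the 6 slides held a single genotype at a single time, with 8 arrays, and each time had its own scan day, 3 in all. Alcohol and control arrays therefore shared slides, while genotypes never did. The 4M slides were extracted with their own protocol, and their E1A spike-in spots lay at log2 -4.52 to -2.93 relative to the array's 75th percentile, against -0.35 to 2.14 on the other slides. Within slides, alcohol and control arrays lay in separate rows in wild type at 1M and in both genotypes at 4M, and nearly so in PPARα-null at 1M.

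Ppara itself measured log2 4.33 ± 0.22 (SD, n = 4, relative to the array's 75th percentile) in wild-type control 1M, 3.19 ± 0.54 at 2M and 5.17 ± 0.39 at 4M. In null control arrays it was 3.19 ± 0.31 at 1M (n = 4, with a left-out spot on the remaining array), 2.86 ± 0.10 at 2M and 2.70 ± 0.29 at 4M. Its 3 probes were well above background on all arrays of both genotypes. Which part of the gene was deleted, and whether the probes lie in it, is not given in the sources used here, so the Ppara signal does not check the genotype. Between genotypes on the control diet Ppara was lower by a mean log2 of -1.31 ± 0.16 (SE, limma adjusted p = 1.77e-07, 2.48-fold, lower in 12 of 12 null arrays), with -1.14 at 1M, -0.33 at 2M and -2.47 at 4M. It was not called for alcohol in wild type (-0.13 ± 0.16, limma adjusted p = 0.672, lower in 7 of 12 arrays) or in PPARα-null (0.07 ± 0.17, limma adjusted p = 0.908), nor for the difference of responses (0.20, limma adjusted p = 0.917).

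Alcohol in wild-type liver raised the ω-hydroxylase genes Cyp4a14, Cyp4a10 and Cyp4a31, which PPARα controls, together with the xenobiotic and female-biased gene lists. It lowered male-specific Hsd3b5, while the male-biased list, with 14 of 15 members lower and 4 called, lost its call with an estimated correlation. Cyp4a14 rose by log2 2.97 ± 0.23 (SE, 12 alcohol against 12 control arrays, limma adjusted p = 4.83e-10, 7.85-fold, higher in 12 of 12 alcohol arrays), by 4.58 at 1M, 2.70 at 2M and 1.65 at 4M. Cyp4a10, its close relative, rose by 2.21 ± 0.24 (limma adjusted p = 1.53e-07, 4.64-fold, 12 of 12), and Cyp4a31 by 2.19 ± 0.23 (7.68e-08, 4.56-fold, 11 of 12). Cyp2b10, the usual target of the xenobiotic receptor CAR, rose by 3.21 ± 0.40 (limma adjusted p = 1.83e-06, 9.29-fold, 12 of 12), with 3.39, 4.12 and 2.14 at the 3 times. Cyp3a11, which metabolizes drugs and steroids, rose by 2.54 ± 0.26 (7.68e-08, 5.82-fold, 12 of 12), and Cyp2c37, an arachidonic acid epoxygenase, rose 3.65-fold (1.87 ± 0.22, 5.28e-07, 12 of 12). Slco1a4, an organic anion uptake carrier, rose by 1.19 ± 0.21 (limma adjusted p = 0.00094, 2.28-fold, 11 of 11 usable arrays). Cyp2a4, a steroid hydroxylase that is female-biased in mice, rose 3.88-fold (1.96 ± 0.22, 3.86e-07, 12 of 12). The sulfotransferase Sult3a1, also female-biased, rose by 4.76 ± 0.62 (limma adjusted p = 4.56e-06, 10 of 12), a size read against background signal since 10 of 12 alcohol and 1 of 12 control arrays were well above it. Male-specific Hsd3b5, a steroid dehydrogenase, fell by 6.53 ± 1.00 (limma adjusted p = 9.79e-05, 92.4-fold, lower in 12 of 12). This size is read partly against background signal, since only 7 of 12 alcohol arrays were above it. Alas2, the erythroid enzyme of heme synthesis, fell by 1.89 ± 0.22 (limma adjusted p = 9.3e-07, 3.69-fold, 12 of 12), and Omd, a small matrix proteoglycan, fell by 2.16 ± 0.27 (1.76e-06, 12 of 12), also read against background signal, with 3 of 12 alcohol and 10 of 12 control arrays well above it.

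Further genes called in wild type included Ehhadh, Gstm4, Cth, Fgg, Apoa4 and C6. Ehhadh and Acox2, both peroxisomal oxidation enzymes, rose by log2 1.00 ± 0.20 (limma adjusted p = 0.00474, 12 of 12 arrays) and 0.90 ± 0.18 (0.00384, 12 of 12). The glutathione transferase Gstm4 rose 2.41-fold (1.27 ± 0.23, limma adjusted p = 0.00158, 12 of 12), and Cth, which makes cysteine for glutathione, rose 2.04-fold (1.03 ± 0.19, 0.00128, 12 of 12). Asns, an amino acid stress gene, rose by 1.01 ± 0.23 (limma adjusted p = 0.0101, 11 of 12), fibrinogen gene Fgg by 0.88 ± 0.17 (0.00197, 11 of 12) and the lipoprotein gene Apoa4 by 1.31 ± 0.22 (0.000642, 12 of 12). Complement gene C6 fell by 1.14 ± 0.20 (limma adjusted p = 0.00101, 12 of 12). Ehhadh, Acox2 and Asns were not called without 1M (0.86, 0.81 and 1.02, limma adjusted p = 0.0832, 0.118 and 0.0637) or without 2M (0.79, 0.75 and 0.91, limma adjusted p = 0.245, 0.0591 and 0.172). Without 1M, C6 (-0.68, limma adjusted p = 0.208) and Sult3a1 (2.58, 0.0835) also lost the call, and without 2M Gstm4 (0.86, 0.182), Fgg (0.62, 0.277), Cth (0.69, 0.18) and Apoa4 (1.17, 0.0543) lost it. The ethanol-oxidizing Cyp2e1 (0.11 ± 0.16, limma adjusted p = 0.733, 6 of 12), the bile acid enzyme Cyp7a1 (-0.63 ± 0.41, 0.406, 9 of 12), the lipogenic regulator Srebf1 (-0.80 ± 0.26, 0.0863, 10 of 12), Tnf (0.10 ± 0.13, 0.685), collagen gene Col1a1 (0.49 ± 0.28, 0.343) and the cell cycle inhibitor Cdkn1a (-0.73 ± 0.42, 0.343) were not called. The hepatokine Fgf21 had no estimate in wild type, and in PPARα-null it measured 0.23 ± 0.44 (limma adjusted p = 0.88). The sex chromosome genes Xist (-0.02 ± 0.23, limma adjusted p = 0.977) and Ddx3y (0.06 ± 0.22, 0.899) were not called.

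Of 34277 genes with an estimate, limma called 743 for alcohol in wild type, 566 higher and 177 lower, with 6401 at an unadjusted p under 0.05. The count was 172 without 1M, 97 without 2M and 742 without 4M. It moved by more than 1.5 times without wild-type control 1M replicate 1 (413), alcohol 1M replicate 3 (436), alcohol 2M replicates 1 (1551), 3 (458) and 4 (369), control 4M replicates 2 (1204) and 4 (415), and alcohol 4M replicate 3 (435). Of the called genes with several probes, 40 of 196 had probes that disagreed.

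Gene lists were tested for the same comparison, and 17 of 36 were called by camera, 16 higher and 1 lower. Xenobiotic P450 and receptor genes had a median of log2 1.34 over 23 tested members, with 13 higher over all genes and 15 adjusted over the list alone (camera adjusted p = 9.16e-39, and adjusted p = 1.66e-05 with an estimated correlation). Female-biased genes had a median of 1.04 over 17, with 9 higher and 11 adjusted over the list alone (4.61e-22, and adjusted p = 1.18e-08 with an estimated correlation). PPARα targets outside β-oxidation had a median of 0.24 and a mean of 0.62 over 26, with 7 higher on either adjustment (6.39e-14, and adjusted p = 0.00547 with an estimated correlation). The remaining 14 calls were lost with an estimated correlation. Among these, male-biased genes had a median of -0.93 (4 of 15 called lower, 8 adjusted over the list alone, camera adjusted p = 1.4e-09, adjusted p = 0.137 with an estimated correlation), acute phase genes 0.56 (6 of 22 called higher, 14 adjusted over the list alone, 3.42e-10, and 0.152) and glutathione genes 0.40 (9 of 28 called higher, 14 adjusted over the list alone, 1.37e-11, and 0.125). Mitochondrial oxidation genes had a median of 0.44 (camera adjusted p = 1.94e-08), unfolded protein response genes 0.41 (5.57e-06), methionine and one-carbon genes 0.36 (1.62e-07) and peroxisomal oxidation genes 0.30 (0.000209, lost without 2M at 0.06 and 0.457). Markers of cell types moved with them, with medians of 0.36 for Kupffer cells (0.000782, lost without 1M at 0.14 and 0.0862), and 0.32 for stellate cells (0.00833), 0.30 for endothelium (0.0146) and 0.21 for hepatocytes (0.00693), all 3 lost without 2M (0.27, 0.19 and -0.02, camera adjusted p = 0.167, 0.225 and 0.52). Lipid droplet (0.26, 0.000592), bile acid synthesis (0.25, 0.00586) and bile acid transport genes (0.11, 0.0299) were also called, and not without 2M (camera adjusted p = 0.0785, 0.729 and 0.744). Cytokine (-0.07, 0.368), matrix and fibrosis (0.11, 0.45), cholesterol synthesis (-0.11, 0.974) and ethanol metabolism genes (0.18, 0.146) were not called. Fry, which does not compare members with other genes, called 12 lists. Of the 14 lists above, it called glutathione (fry adjusted p = 0.00482), methionine (0.00682), male-biased (0.00973), lipid droplet (0.01) and acute phase genes (0.0101). Unfolded protein response (0.0264), peroxisomal (0.02865) and mitochondrial oxidation genes (0.0369) were called by fry too.

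**Figure D1:**
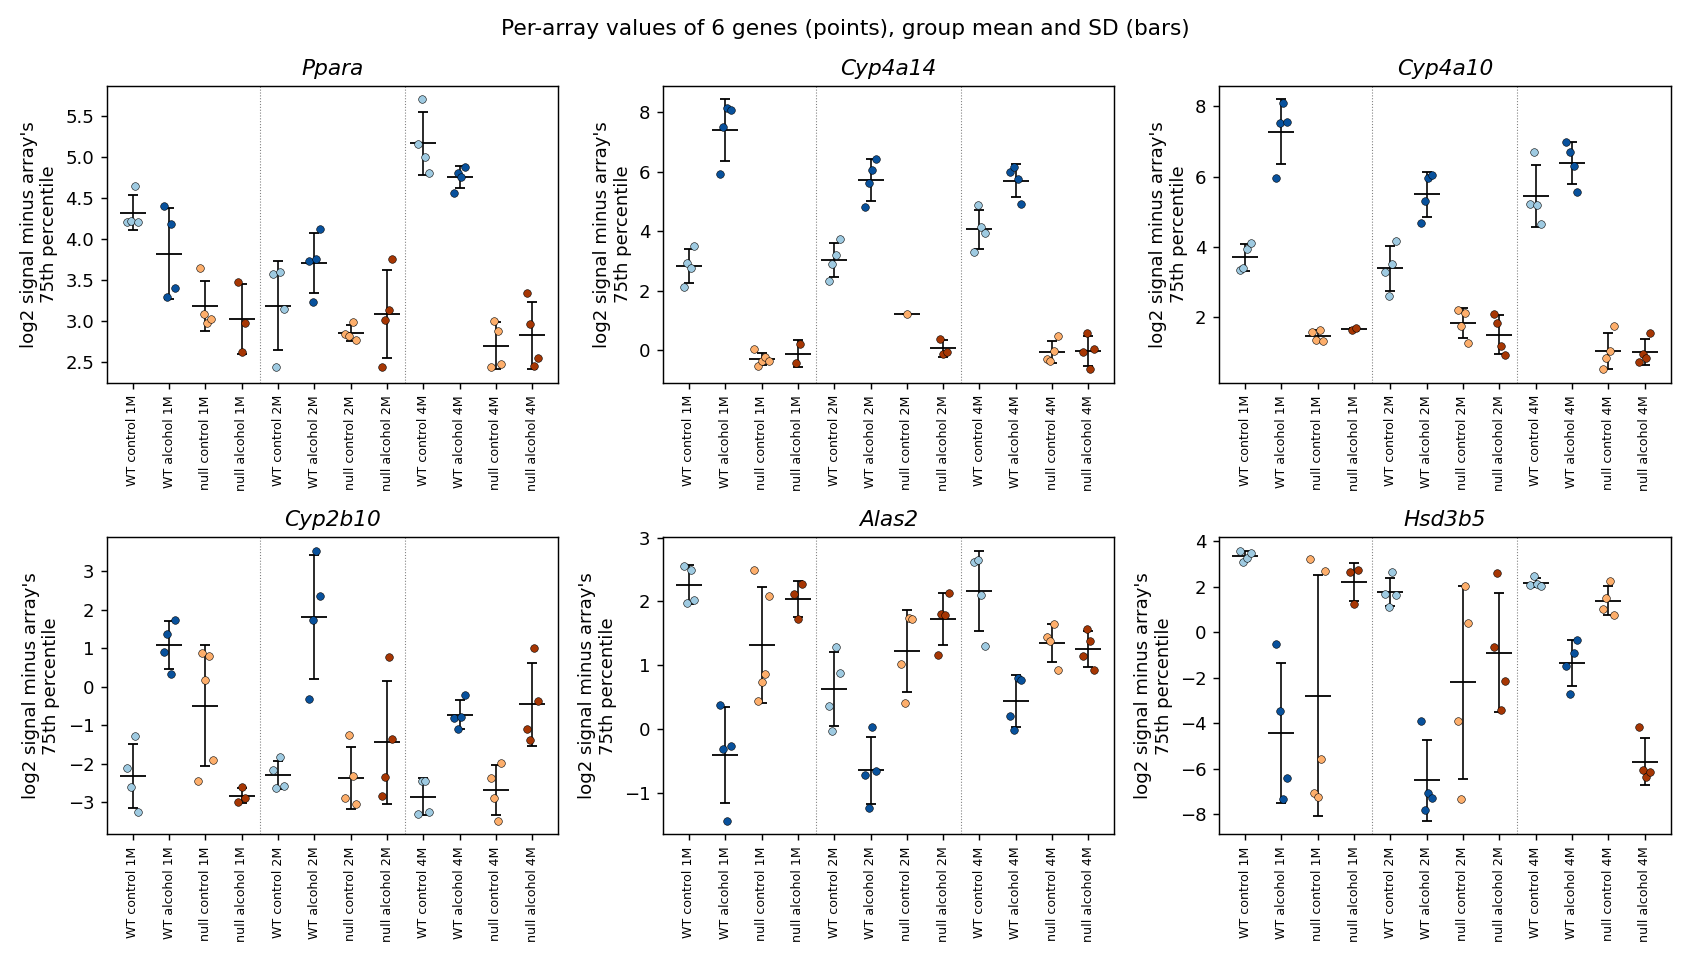
Log2 signal relative to each array's 75th percentile for 6 genes, by group, with points for arrays and bars for the mean and SD. Cyp4a14 averaged 7.41 in wild-type alcohol 1M against 2.83 in its controls, and Hsd3b5 spread widely within null control 1M (SD 5.29).

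At single times, which compare arrays of the same slide, the wild-type response was largest at 2M by count. Limma called 83 genes at 1M (51 higher, 32 lower), 1535 at 2M (1162 higher, 373 lower) and 12 at 4M, all higher. This order turned with array weights, which gave 1243, 994 and 1463. The excess of higher calls at 1M was lost in 2 alternatives. Among genes well above background on all 48 arrays 45.2% of 84 calls were higher, and without 3 doubted arrays 49.7% of 157. Sult3a1 rose at least 271-fold at 1M, a bound since 0 of 4 control arrays were well above background (log2 9.14 ± 1.07, limma adjusted p = 1.33e-06). At 1M Omd fell at least 3.95-fold (-2.79 ± 0.46, limma adjusted p = 0.00135) and Alas2 fell by 2.67 ± 0.39 (0.000105). Cyp2b10 (4.12 ± 0.69, limma adjusted p = 0.00111) rose at 2M, where Hsd3b5 fell by 8.28 ± 1.73 (0.00681), a size read against signal at background since 1 of 4 alcohol arrays was well above it. Cyp3a11 rose by 2.67 ± 0.46 at 4M (limma adjusted p = 0.00583). In fits on the compared groups alone the calls of Sult3a1, Omd and Alas2 at 1M (limma adjusted p = 0.0864, 0.0786 and 0.104), Cyp2b10 at 2M (0.123) and Cyp3a11 at 4M (0.121) ended. That of Cyp3a11 also ended with the row as a covariate (2.03, 0.229) and with the mean of probes (2.41, 0.0535). Xenobiotic genes had medians of 1.02, 1.82 and 0.88 (camera adjusted p = 1.1e-19, 9.25e-26 and 3.74e-09), female-biased genes 1.87, 0.96 and 0.42 (5.45e-33, 2.25e-06 and 0.000193), and PPARα targets 0.56, 0.70 and -0.06 (2.1e-19, 1.64e-07 and 0.459). The camera direction of PPARα targets at 4M was upward against that negative median. Skeletal muscle markers had a median of 2.14 at 1M (camera adjusted p = 1.34e-13), -0.34 at 2M and -0.86 at 4M (0.00101), and Kupffer cell markers 0.89 (4.45e-08), 0.59 (0.00874) and -0.22. At 2M hepatocyte markers had a median of 0.76 (camera adjusted p = 2.4e-07), above that of PPARα targets. Stellate (0.45, 0.00482) and endothelial markers (0.43, 0.00893) were also called. The F test called 1 gene, the mucosal scavenger gene Dmbt1 (limma adjusted p = 0.00522), for a response that differed between times, so differences in count between times are not shown to be differences in response.

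These single-time counts were sensitive to arrays. At 1M the count was 20, 29, 45 and 33 without wild-type control replicates 1 to 4, and 206, 36 and 20 without alcohol replicates 1, 3 and 4. At 2M it was 706 and 492 without control replicates 2 and 4, and 3771, 393 and 105 without alcohol replicates 1, 3 and 4. At 4M it was 5 and 198 without control replicates 2 and 4, and 4, 5 and 19 without alcohol replicates 2, 3 and 4. With normexp and quantile normalization, the 4M calls numbered 3 higher and 2 lower.

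In PPARα-null liver no Cyp4a gene tested here and no member of the xenobiotic list was called by limma on the mean of the 3 times. Cyp4a14 measured log2 -0.32 ± 0.30 (SE, 11 alcohol against 13 control arrays, limma adjusted p = 0.773) and lay near the array's 75th percentile in null groups with several usable arrays, for example -0.05 ± 0.37 (SD, n = 4) in null control 4M against 4.06 ± 0.65 in wild-type control 4M. At 2M a single null control array gave a usable Cyp4a14 value. Cyp4a10 (-0.06 ± 0.25, limma adjusted p = 0.949), Cyp2b10 (0.28 ± 0.40, 0.836), Alas2 (0.37 ± 0.23, 0.707), Hsd3b5 (-0.25 ± 1.01, 0.941) and Cyp3a11 (1.05 ± 0.27, 0.392, higher in 6 of 11 arrays) were not called. Neither were Col1a1 (0.87 ± 0.29, limma adjusted p = 0.519, 10 of 11), Cyp2e1 (0.17 ± 0.16, 0.772), Srebf1 (0.47 ± 0.26, 0.693), Cyp7a1 (-0.23 ± 0.42, 0.868), Tnf (0.29 ± 0.13, 0.669), Cdkn1a (-0.61 ± 0.48, 0.74), Xist (0.01 ± 0.25, 0.989) or Ddx3y (0.15 ± 0.22, 0.841). Of 33303 genes, limma called 1, with 2452 at an unadjusted p under 0.05. With array weights it called 12259 (8379 higher, 3880 lower). The 1 gene called without weights was Gabpa, a transcription factor of mitochondrial genes, named after its value was seen (-2.00 ± 0.31, limma adjusted p = 0.0146, 3.99-fold lower). Its probes disagreed, and its call rested on 2 usable arrays in each 2M group. The limma count was 5 without 1M, 5 without 2M and 2 without 4M. It was 0 without null control 1M replicate 2, alcohol 1M replicate 3, control 2M replicates 1 and 4, or alcohol 2M replicates 3 and 4 (2241, 2011, 1961, 2242, 1606 and 1598 genes at an unadjusted p under 0.05), 2 without alcohol 2M replicate 2, and 4 without alcohol 4M replicate 4.

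Camera called 4 lists in PPARα-null, all higher and none with an estimated correlation. Xenobiotic genes had a median of log2 0.28 over 23 members (camera adjusted p = 8.37e-05, adjusted p = 0.649 with an estimated correlation) and glutathione genes 0.27 over 28 (the same values), each with 0 members called by limma over all genes and 2 adjusted over the list alone. Ethanol and aldehyde metabolism genes had a median of 0.18 (camera adjusted p = 0.0391, adjusted p = 0.649 with an estimated correlation) and Kupffer cell markers 0.32 (0.0391, and 0.809). Without 4M all 4 calls were lost, at medians of -0.06, 0.01, 0.08 and 0.01 (camera adjusted p = 0.113, 0.899, 0.501 and 0.821), and without 2M those of ethanol genes and Kupffer markers (0.15 and 0.34, both camera adjusted p = 0.17). PPARα targets (0.07, camera adjusted p = 0.871) and female-biased genes (-0.08, 0.235) were not called.

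Within slides, the null arrays of the 3 times went different ways. Xenobiotic genes had medians of log2 -0.45 on the arrays labelled 1M, 0.23 at 2M and 1.13 at 4M (camera adjusted p = 7.33e-07, 0.0718 and 3.37e-16), and glutathione genes -0.44, 0.54 and 0.73 (2.24e-06, 0.000128 and 1.03e-09). Hepatocyte markers had medians of the same signs, -0.29, 0.21 and 0.36 (camera adjusted p = 0.00204, 0.0865 and 0.00539). So did Kupffer cell markers, at -0.24, 0.37 and 0.83 (0.0869, 0.0865 and 0.00142). Cyp2b10 measured -2.33, 0.94 and 2.22 (limma adjusted p = 0.469, 0.586 and 0.124), and Hsd3b5 5.01, 1.31 and -7.07 (0.541, 0.749 and 0.0505). At 4M Cyp3a11 (3.17, limma adjusted p = 0.000449), Gstm3 (2.21, 0.00193), the epoxygenase Cyp2c38 (3.17 ± 0.47, 0.000512), the steroid hydroxylase Cyp3a41b (3.20 ± 0.52, 0.00121) and the retinoic acid hydroxylase Cyp26a1 (3.47 ± 0.61, 0.00307, at least 5.81-fold) rose. Cyp3a41b was above background on 1 of 4 control arrays. With the row as a covariate, which coincides with diet at 4M, 0 genes were called at 4M (2697 at an unadjusted p under 0.05), so all 5 lost the call, among them Cyp26a1 (limma adjusted p = 0.183), Cyp3a41b (0.178) and Cyp2c38 (0.148). Cyp26a1 was not called in a fit on the compared groups alone either (limma adjusted p = 0.133). Of the 743 genes called in wild type, 11.8%, 87.5% and 83.9% had the wild-type direction in null at 1M, 2M and 4M. Limma called 0 genes at 1M (2767 at an unadjusted p under 0.05), 31 at 2M (1 higher, 30 lower) and 130 at 4M (89 higher, 41 lower). The direction at 2M turned with array weights, where 63.6% of 13697 calls were higher. The F test called 88 genes for a response that differed between times, among them Cyp26a1 (limma adjusted p = 0.00581), Cyp2c38 (0.00128) and Hsd3b5 (0.0331). At 4M the median gene lay at 0.12, and the split was 68 higher and 84 lower with normexp and quantile normalization and 71 higher and 12 lower on the authors' values. At 1M the limma count was 7 without null control replicate 4 and 3 without alcohol replicate 1. At 2M it was 5, 12 and 17 without control replicates 1, 3 and 4, and 192, 78, 0 and 0 without alcohol replicates 1 to 4. At 4M it was 68, 62 and 33 without control replicates 1, 3 and 4, and 27, 35, 28 and 1079 without alcohol replicates 1 to 4.

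The difference of the responses, which asks whether the effect of alcohol depends on PPARα, was called mainly for genes that alcohol raised in wild type. As null minus wild type, Cyp4a14 measured log2 -3.29 ± 0.38 (SE, limma adjusted p = 1.52e-05), Cyp4a10 -2.27 ± 0.35 (0.000709) and Cyp4a31 -2.12 ± 0.32 (0.000699). Cyp2b10 measured -2.94 ± 0.57 (limma adjusted p = 0.0202) and Cyp2c37 -1.59 ± 0.31 (0.0202). Sult3a1 measured -5.26 ± 0.88 (limma adjusted p = 0.00271), a size that rests on signal near background in most null arrays, with arrays well above it numbering 2 of 5, 1 of 4 and 0 of 4 in null control and 1 of 3, 1 of 4 and 1 of 4 in null alcohol at the 3 times. The hepatokine Fgl1 measured -2.89 ± 0.51 (limma adjusted p = 0.00712) and the translation repressor gene Eif4ebp3 -1.87 ± 0.38 (0.0314), while Alas2 (2.26 ± 0.32, 0.000173) and Omd (2.22 ± 0.38, 0.00372) differed upward. Not called were Hsd3b5 (6.28 ± 1.42, limma adjusted p = 0.0903), Cyp3a11 (-1.50, 0.164), Cyp2a4 (-1.49, 0.0596), Apoa4 (-1.42, 0.0903), Slco1a4 (-1.16, 0.177), C6 (1.24, 0.105) and Srebf1 (1.28 ± 0.37, 0.327). Limma called 13 of 33201 genes, 3 higher and 10 lower (1 higher and 11 lower with normexp and quantile normalization), with 2425 at an unadjusted p under 0.05. The predominant direction turned with array weights (2920 higher and 906 lower) and without 3 doubted arrays (17 higher and 10 lower). It called 0 without 1M (1572 at an unadjusted p under 0.05), 4 without 2M and 51 without 4M, and 20, 21 and 26 without wild-type alcohol 1M replicate 1, wild-type control 2M replicate 1 and null alcohol 2M replicate 3. Without 1M, where the null arrays ran against the other times, Cyp4a14 measured -2.73 (limma adjusted p = 0.129), Alas2 1.69 (0.343), Cyp4a10 -1.71 (0.855), Cyp4a31 -1.36 (0.855), Sult3a1 -3.44 (0.985), Omd 1.84 (0.982), Cyp2b10 -1.55 (1), Cyp2c37 -0.89 (1), Fgl1 -1.65 (1) and Eif4ebp3 -2.02 (0.343). Without 2M, calls ended for Cyp4a10 (-2.18, limma adjusted p = 0.0901), Cyp4a31 (-2.30, 0.0629), Sult3a1 (-5.50, 0.0824), Cyp2b10 (-2.82, 0.158), Cyp2c37 (-1.30, 0.182), Fgl1 (-3.14, 0.0728) and Eif4ebp3 (-2.14, 0.0886). By single time, limma called 34 genes at 1M (6 higher, 28 lower), and 0 at 2M and 0 at 4M with 1513 and 3015 at an unadjusted p under 0.05.

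Among the lists, 14 differed between the responses by camera, 4 higher and 10 lower in null. Female-biased genes had a median difference of log2 -1.12 (2 of 17 called lower, 12 adjusted over the list alone, camera adjusted p = 6.77e-26, and adjusted p = 2.51e-10 with an estimated correlation). Xenobiotic genes had -1.10 (2 of 23 called lower, 12 adjusted over the list alone, 5.09e-21, and adjusted p = 0.00614 with an estimated correlation) and PPARα targets -0.18 (3 of 25 called lower, 5 adjusted over the list alone, 6.89e-10, and 0.0375). By time, xenobiotic genes had a lower median in null than in wild type at 1M (-0.45 and 1.02), where null arrays ran against the other times. It was lower at 2M (0.23 and 1.82) and higher at 4M (1.13 and 0.88). PPARα targets ran the same way, lower in null at 1M (-0.26 and 0.56) and 2M (0.27 and 0.70) and higher at 4M (0.17 and -0.06). Female-biased genes were lower in null at all 3 times (-0.42 and 1.87, -0.40 and 0.96, and 0.23 and 0.42). The other 11 calls were lost with an estimated correlation. They included acute phase genes (-0.48, camera adjusted p = 6.1e-12, adjusted p = 0.178 with an estimated correlation), male-biased genes (0.50, 2.01e-08, and 0.205) and fatty acid synthesis genes (0.37, 0.000417, and 0.356). Without 1M, acute phase (-0.09, camera adjusted p = 0.0891) and fatty acid synthesis genes (0.33, 0.0684) were not called.

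On the control diet, the arrays of PPARα-null liver had lower values than those of wild type for peroxisomal oxidation genes, PPARα targets and fatty acid synthesis genes, the 3 lists that kept their call with an estimated correlation. Slide and genotype coincide, so the limma adjusted p with slide as a random block is given beside each gene. That fit held genotype and diet but not time, so its spread between slides includes differences between times. It took 1 correlation (0.362) for all genes and its degrees of freedom from arrays, although genotype varies only between slides. Its p-values therefore do not take the slide as the unit. With 1 mean per slide, also without time, limma adjusted p was 0.622 for Vnn1 and Fitm1. It was 0.772 for the other genes of this paragraph. Cpt2, the inner-membrane carnitine transferase, fell by log2 2.31 ± 0.17 (SE, 12 against 13 arrays, limma adjusted p = 1.75e-12, 4.95-fold, lower in 13 of 13 null arrays, and 0.000134 with slide as a random block), by 2.00, 1.57 and 3.36 at 1M, 2M and 4M. Eci2, a peroxisomal isomerase, fell by 2.13 ± 0.17 (8.83e-12, 4.37-fold, 12 of 12, block 0.000134) and Hsd17b4, also of peroxisomal oxidation, by 1.86 ± 0.15 (1.92e-11, 13 of 13, block 0.000922). The PPARα targets Cyp4a14 (-3.02 ± 0.28, limma adjusted p = 2.08e-09, 8.12-fold, 10 of 10 usable arrays, block 0.00105), Cyp4a10 (-2.73 ± 0.24, 1.54e-10, 6.64-fold, 12 of 12, block 0.00404) and the pantetheinase Vnn1 (-3.39 ± 0.21, 1.13e-14, 10.5-fold, 13 of 13, block 3.85e-06) fell. Among lipid droplet genes, a list that was not called (4 higher and 6 lower, camera adjusted p = 0.16), Plin5 (-2.16 ± 0.26, limma adjusted p = 1.49e-07, 4.45-fold, 13 of 13, block 0.0267) and Fitm1 (-5.13 ± 0.38, 1.75e-12, 13 of 13, block 4.1e-05, above background on 3 of 13 null arrays) fell. In the same list Apoa4 (limma 1.20, 7.43e-05, 13 of 13, block 0.197, and without 2M 0.57 and 0.0709) and Cidea (0.93, 0.000289, 10 of 10 usable arrays, block 0.213) rose. In fat synthesis the desaturase Scd1 fell by 3.37 ± 0.32 (limma adjusted p = 5.47e-10, 10.4-fold, 13 of 13, block 0.0163), the NADPH-supplying Me1 by 3.21 ± 0.25 (8.83e-12, 9.27-fold, 13 of 13, block 0.00861) and Srebf1 by 2.41 ± 0.26 (8.88e-09, 5.32-fold, 13 of 13, block 0.0131).

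Other genotype differences were called without and not with the slide block. The cholesterol synthesis gene Fdps (-2.30 ± 0.30, limma adjusted p = 6.39e-07, 13 of 13, block 0.0874), the bile acid genes Cyp7a1 (-1.98 ± 0.41, 0.000272, 12 of 13, block 0.201, and without 4M -1.32 and 0.103) and Baat (-1.02 ± 0.17, 1.39e-05, block 0.218), the sterol exporter gene Abcg5 (-1.62 ± 0.20, 2.2e-07, block 0.0532) and the glycogen enzyme gene Pygl (-1.69 ± 0.17, 2.08e-09, 13 of 13, block 0.0514) were lower. Ppara (block 0.0589) and the Y-linked Ddx3y (-1.30 ± 0.21, limma adjusted p = 2.03e-05, 13 of 13, block 0.144) were lower too. The complement gene C1qa (1.71 ± 0.28, limma adjusted p = 2.1e-05, 13 of 13, block 0.156), the macrophage lysozyme gene Lyz2 (1.92 ± 0.32, 2.39e-05, 13 of 13, block 0.127), the antigen-presenting H2-Aa (1.77 ± 0.35, 0.000183, 13 of 13, block 0.177), the acute phase gene Saa3 (2.02 ± 0.33, 1.89e-05, 12 of 13, block 0.136), the estrogen sulfotransferase gene Sult1e1 (2.78 ± 0.37, 6.56e-07, 13 of 13, block 0.0942) and Col1a1 (1.34 ± 0.29, 0.000422, 10 of 12, block 0.264, and without 4M 0.74 and 0.196) were higher. Cyp2e1 (-0.73 ± 0.16, limma adjusted p = 0.000553, 10 of 13, block 0.294) was not called with normexp (-0.11, 0.234), with quantile normalization (-0.15, 0.152) or without 4M (-0.29, 0.358). Cyp2b10 (0.64 ± 0.39, limma adjusted p = 0.201), Tnf (-0.18, 0.276), Cdkn1a (1.10 ± 0.49, 0.0763) and Xist (0.42 ± 0.23, 0.154) were not called. Limma called 12700 of 33760 genes, 4868 higher and 7832 lower, with 15743 at an unadjusted p under 0.05, and 5853 higher and 6383 lower relative to the median gene (-0.08). Of calls with a log2 change of at least 1, most were higher in null (2274 against 1186 lower). With slide as a random block it called 116, 6 higher and 110 lower, and from slide means it called 0, with 1503 at an unadjusted p under 0.05. Both fits left out the time, so these counts do not show the effect of slide alone. With the genotype of the 2M slides exchanged limma called 14924, more than with the real labels. It called 1764 and 2177 with the 1M or the 4M slides exchanged. By time it called 4751 at 1M (2152 higher, 2599 lower), 4093 at 2M (1609 higher, 2484 lower) and 15866 at 4M (7474 higher, 8392 lower). The count over all times was 6760 without 1M, 18203 without 2M and 3309 without 4M. Of the called genes with several probes, 1712 of 3500 had probes that disagreed.

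Of the lists, 20 differed between genotypes by camera, 7 higher and 13 lower in null. All 20 were also called with slide as a random block, at the preset correlation. Camera takes its p from a comparison between genes, so these block values do not test slide against genotype. With the slide as the unit, the exact two-sided permutation p was 0.2 for peroxisomal and mitochondrial oxidation genes and 0.1 for PPARα targets, where 0.1 is the smallest that 3 slides against 3 allow. This test compared slides across times and left out that each slide has a counterpart of the other genotype at the same time. Peroxisomal oxidation genes had a median of log2 -1.03 (14 of 20 called lower and 1 higher over all genes and adjusted over the list alone, camera adjusted p = 6.07e-12, adjusted p = 0.0186 with an estimated correlation, block 6.96e-11). The difference was -0.87 at 1M, -0.13 at 2M and -2.04 at 4M, against -0.99, -0.24 and -1.96 for mitochondrial oxidation genes and -0.89, -0.25 and -1.64 for PPARα targets. Fatty acid synthesis genes had -1.20 (18 of 23 called lower over all genes and adjusted over the list alone, 1.09e-13, and adjusted p = 0.0186 with an estimated correlation), and PPARα targets -0.68 (15 of 26 called lower, 1.37e-10, and 0.0299). The other 17 calls were lost with an estimated correlation, among them mitochondrial oxidation genes (-1.01, 19 of 22 called lower, 20 adjusted over the list alone, camera adjusted p = 2.57e-18, adjusted p = 0.0838 with an estimated correlation), cholesterol synthesis genes (-1.23, 19 of 24 called lower, 21 adjusted over the list alone, 1.01e-09, and 0.179) and gluconeogenesis genes (-0.93, 2.21e-06, and 0.0982). Markers of hepatocytes had a median of -0.76 (14 of 15 called lower, camera adjusted p = 1.71e-09), and those of Kupffer cells 0.72 (9 of 14 called higher, 2.07e-05), T and NK cells 0.35 (0.0139) and B and plasma cells 0.66 (0.0193). Monocyte and neutrophil (-0.10, 0.411), endothelial (-0.21, 0.337), stellate (0.19, 0.232) and cholangiocyte markers (-0.11, 0.902) were not called. Cytokine genes (0.32, camera adjusted p = 0.00672) and interferon-stimulated genes (0.35, 0.0209) were higher, and ethanol metabolism genes (-0.46, 0.00925) and male-biased genes (-0.51, 0.0139) lower. Without 4M the call of ethanol genes ended (-0.29, camera adjusted p = 0.295), as it did with normexp (-0.17, 0.0683). Without 1M those of interferon-stimulated (0.24, camera adjusted p = 0.0891), male-biased (-0.43, 0.0678) and B and plasma cell genes (0.52, 0.0531) ended, and without 2M those of cytokine (0.41, 0.0654), interferon-stimulated (0.47, 0.0654) and B and plasma cell genes (0.58, 0.0761).

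**Figure D2:**
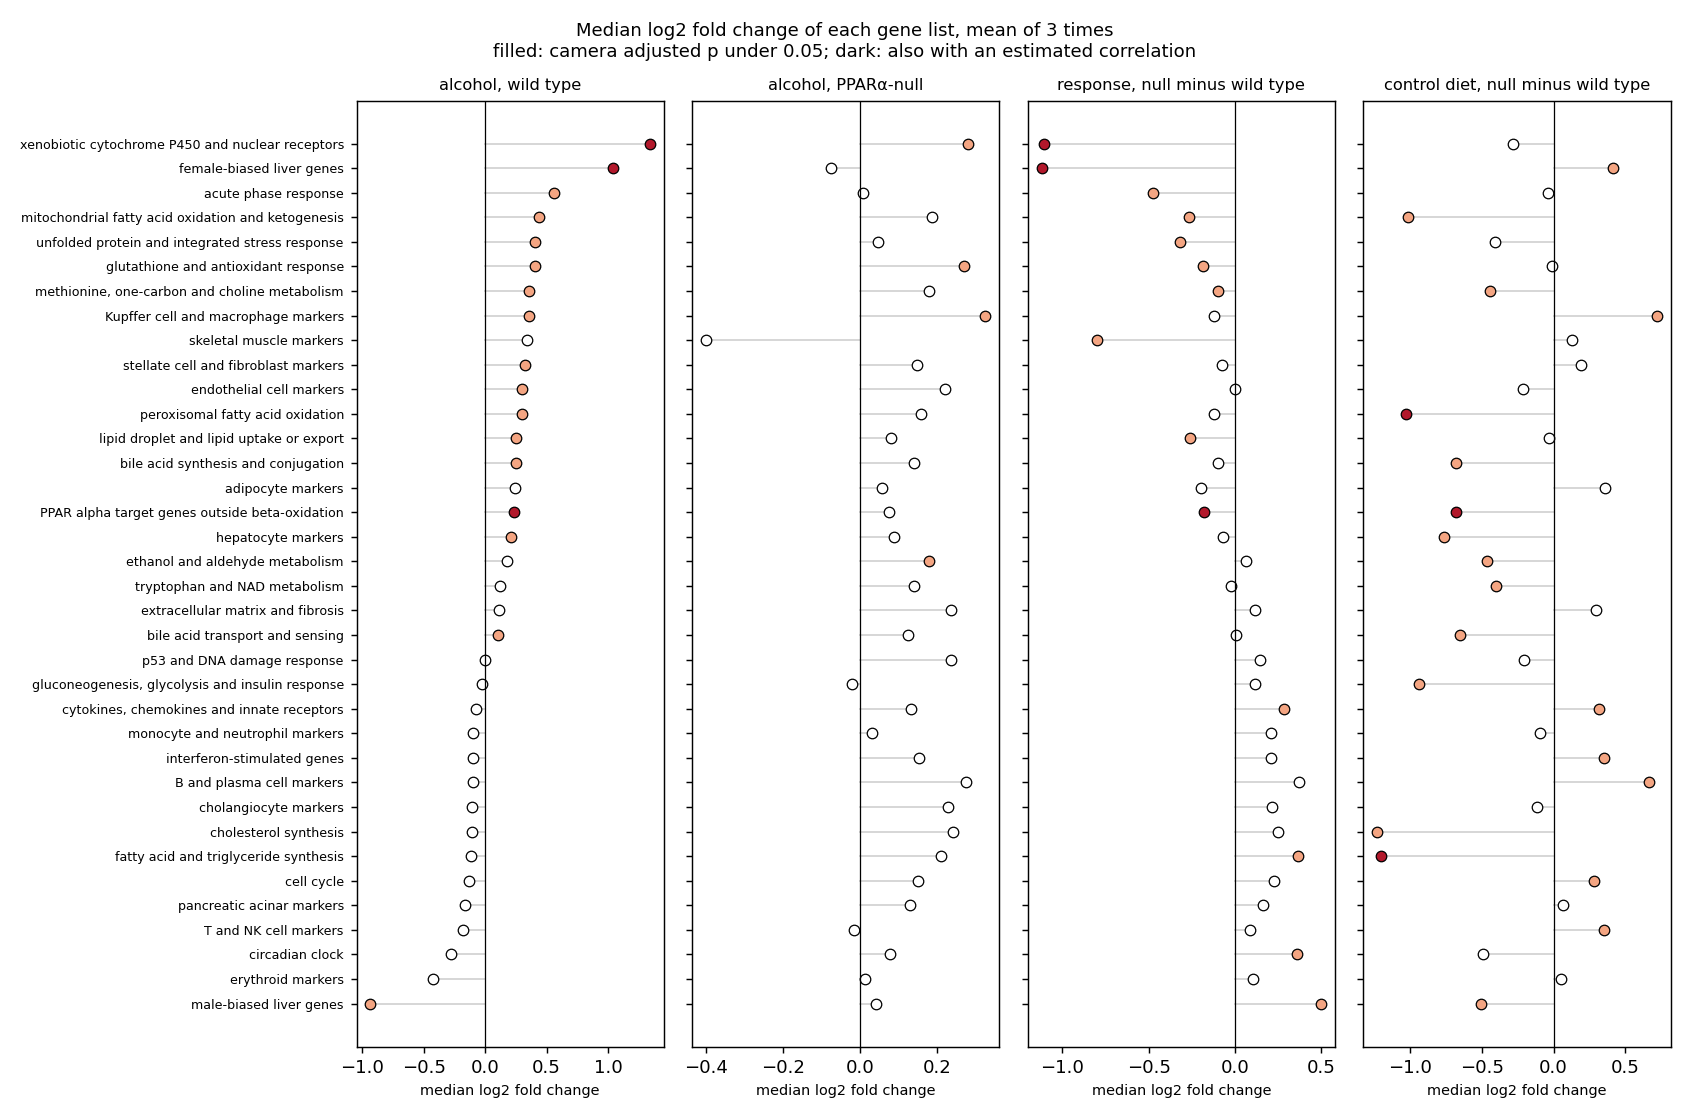
Median log2 fold change of each of 36 gene lists in 4 comparisons, with filled points for a camera adjusted p under 0.05 and dark points where the call also holds with an estimated correlation. Xenobiotic genes reach 1.34 for alcohol in wild type and 0.28 in PPARα-null.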

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

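Apart from the other splits of the samples, the tests of explanations here were chosen after the result, or values related to it, had been seen. The test of the direction of change on the null 1M slide and that of overlap between slides in the lists were added when their results were known. The exchange of whole slides was added when the differences between slides were known.

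Over 75 tests of a group of arrays, spread over 7 measures, 6 arrays lay far from the rest of their group, and chance marks about 1 in 20 tests. The 75th percentile of intensity was 1319 on wild-type alcohol 1M replicate 2 (others 894 to 918), 3305 on wild-type control 2M replicate 2 (1083 to 1237) and 2978 on null alcohol 2M replicate 1 (1285 to 1365). Ppara measured log2 4.65 on wild-type control 1M replicate 3 (4.21 to 4.23) and 3.64 on null control 1M replicate 1 (2.98 to 3.09). Hsd3b5 measured -4.16 on null alcohol 4M replicate 1 (-6.39 to -6.06).

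The response to alcohol differed between genotypes for 13 genes by limma's test of the difference itself. Among them, as null minus wild type, were Alas2 (2.26), Omd (2.22), Sult3a1 (-5.26), Cyp4a14 (-3.29), Fgl1 (-2.89), Cyp4a10 (-2.27), Cyp4a31 (-2.12), Eif4ebp3 (-1.87), Cyp2c37 (-1.59) and Cyp2b10 (-2.94). Between times, the response differed for 1 gene in wild type and for 88 in PPARα-null.

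Other splits of the same arrays into groups of the same sizes were counted for each result. Chance can be excluded for alcohol in wild type on the mean of 3 times (743 genes, highest other split 19, and 1 of 100 splits as large, the real split included). In wild type at 1M (83, highest other 14, 1 of 35) only the real split gave as many genes, the smallest share these splits allow. No adjustment was made over the results tested. For the difference of responses (13, highest other 4, 1 of 100), the splits exchanged diets in both genotypes and so removed any shared response. They therefore cannot exclude chance for a difference between responses. For genotype (12700, highest other 9671, 1 of 100) chance can be excluded only for arrays taken as exchangeable. Genotypes sit on separate slides, and exchanging the genotype of the 2M slides called 14924 genes, so chance between slides is not excluded. It cannot be excluded in wild type at 2M (1535, highest other 1882, 2 of 35) or 4M (12, highest other 515, 5 of 35). For PPARα-null at 1M the real count was 0 by limma (2767 at an unadjusted p under 0.05, highest other 278), which every split reaches (56 of 56), so the splits say nothing about chance there. In PPARα-null it cannot be excluded at 2M (31, highest other 374, 9 of 35), 4M (130, highest other 323, 3 of 35) or on the mean (1, highest other 2019, 16 of 100). Nor can it be excluded for responses that differ between times in wild type (1, highest other 728, 30 of 100) and PPARα-null (88, highest other 224, 5 of 100). Splits that called several times the real count point to a structure of the samples that the groups leave out. The highest split at wild type 4M put control replicate 4, with few probes above background, with alcohol replicates 2 to 4. At wild type 2M the highest split exceeded the real count by less (1882 against 1535). It put control replicate 2, the array of outlying intensity, with alcohol replicates 2 to 4.

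On the null 1M slide, arrays ran against their labels: 23.3% of the genes called in null at 4M changed in the 4M direction, and Hsd3b5 measured log2 3.21, -7.09, -7.24, -5.57 and 2.69 on the arrays labelled control replicates 1 to 5 and 2.66, 1.24 and 2.73 on those labelled alcohol. A score of the 31 genes called in the same direction in wild type and in null at 4M, centred per slide, lay at 0.137 to 0.487 on all 5 arrays labelled control and at -0.648 to -0.203 on all 3 labelled alcohol, and its SD among the former (0.134, the largest other control group 0.412) decides nothing, since an absent response and a full exchange of labels both predict it. An absent response stays open: 11.8% of the genes called in wild type kept their direction, a share that only the real split of 56 reached, but the next split gave 12.4% and the slide was picked among 3 null slides. Mislabelled arrays cannot be told apart from other causes, since 3 of 56 splits gave as low a share of the genes called at 4M (19.2% to 77.7% over splits). The row on the slide also stays open, since 73.0% of the genes differed between rows at 2M as the labels do at 1M. In the score, that difference at 2M was largest in null alcohol and ran the other way in null control, as given below for 4M. Wild-type diets exchanged rows, with alcohol in row 1 at 1M and in row 2 at 4M. The mean score of wild-type alcohol was higher both times (0.478 against -0.478, and 0.424 against -0.424). This argues against a row effect shared by all slides that outweighs alcohol. The genes were chosen partly by that response, and a smaller row effect, or one of null slides alone, stays open. Single arrays at 1M went both ways on a row effect. The array labelled control replicate 1 shares its row with all 3 labelled alcohol. It matched them in Hsd3b5 (3.21) and in Cyp2b10, given in the last paragraph, but not in the score (0.198). Replicate 5 shares its row with replicates 2 to 4 and the sign of their score (0.137), but not their Hsd3b5 (2.69). In Hsd3b5 and Cyp2b10, control replicates 2 to 4 stood apart from all other arrays of the slide.

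In the genotype difference on the control diet, 12700 genes were called without and 116 with slide as a random block, the latter in a fit that left out the time. A difference between slides could account for much of the count, since slides of the same genotype differed in 1083 to 17705 genes and slide and genotype coincide. Slides of the same genotype are also of different times, so these counts include time. A slide difference stays open for the peroxisomal and mitochondrial lists too, where the lowest wild-type slide lay below the highest null slide in list median (a difference of log2 -0.09 in the closer list). This comparison takes slides of all times together. At matched times, with a single slide of each genotype, null was lower at 1M, 2M and 4M in both lists (-0.87, -0.13 and -2.04, and -0.99, -0.24 and -1.96). For PPARα targets a slide difference cannot be told apart from genotype: all wild-type slides lay above all null slides, by 0.14, but slides of the same genotype, of different times, differed by up to 1.22. The loss of PPARα, which the groups name, stays open beside it as a hypothesis.

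In PPARα-null at 4M, 130 genes were called, and 33 without null control 4M replicate 4, an array with few probes above background. This does not single out that array, since leaving out alcohol 4M replicates 1, 2 or 3 gave 27, 35 and 28, and the fit without all 3 doubted arrays gave 82. The row on the slide might contribute, since 86.6% of the genes differed between rows at 2M in the direction of the 4M change, where limma called 0 of 34339 genes between rows (7556 at an unadjusted p under 0.05). That share averages over the groups at 2M, which went different ways in the 31-gene score. Null alcohol rose from row 1 (-0.325 and -0.699) to row 2 (1.015 and 1.041), and wild-type alcohol also rose (0.431 and 1.026 against 1.272 and 1.221). Null control fell (-0.032 and 0.12 against -0.8 and -0.32), and wild-type control arrays overlapped between rows (-0.919 and -1.158 against -0.708 and -1.164). In wild type, where diets exchanged rows between 1M and 4M, the score kept its sign, as given above. A response to alcohol, which the groups name, stays open beside both.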

How the results depend on the processing

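Spots marked as non-uniform kept, the fit without 3 doubted arrays (wild-type control 2M replicate 2, wild-type control 4M replicate 4 and null control 4M replicate 4) and the genotype difference relative to the median gene were chosen after seeing the data, and the other alternatives were planned. Counts below are genes called by limma, and where a count moved by more than 1.5 times the cause was not tested unless the alternative itself removes arrays or genes.

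Among the scalings, normexp with quantile normalization gave 1128 genes for alcohol in wild type against 743, 3371 at 2M against 1535, 5 at 4M against 12, 58 in PPARα-null at 2M against 31, and for responses that differ between times 49 in wild type against 1 and 177 in PPARα-null against 88. Quantile normalization of the processed signal gave 48 at 1M and 2780 at 2M in wild type, 219 in PPARα-null at 4M against 130, and 13 for differing times in wild type. The authors' values gave 3 in wild type at 4M, 2 in PPARα-null at 1M against 0, 83 at 4M, 3 for differing times in wild type, and 0 for alcohol in PPARα-null against 1 (2063 at an unadjusted p under 0.05).

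Among the filters, genes well above background on all 48 arrays gave 8354 for genotype against 12700, 1 in wild type at 4M, 79 in PPARα-null at 2M and 217 for differing times in PPARα-null, over fewer genes tested. Without a filter, every count stayed within 1.5 times. The mean of a gene's probes gave 0 for alcohol in PPARα-null (2645 at an unadjusted p under 0.05), 5 in wild type at 4M and 65 in PPARα-null at 2M. A minimum log2 change of 1 left 216 for alcohol in wild type and 3460 for genotype. Non-uniform spots kept gave 0 for alcohol in PPARα-null (2298 at an unadjusted p under 0.05), 5 in wild type at 4M, 84 and 47 in PPARα-null at 2M and 4M, and 3 and 33 for differing times in wild type and PPARα-null.

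In the model, a fit on only the groups compared, with fewer arrays behind each variance, gave 480 for alcohol in wild type and, at its single times, 0, 3 and 0 (5404 and 2172 at an unadjusted p under 0.05 at 1M and 4M). In PPARα-null it gave 0 on the mean (2532), 0 at 2M (2403) and 10 at 4M, and for differing times 5 in wild type and 1 in PPARα-null. The row on the slide as a covariate gave 20 for the difference of responses against 13, 245 in wild type at 1M against 83, 0 at 4M (3399), 13 in PPARα-null at 2M, 0 at 4M (2697), and for differing times 20 in wild type and 0 in PPARα-null (2705). Row and diet coincide on the 4M slides and on the wild-type 1M slide, so the row term applied there comes from the other slides. The calls lost at 4M therefore do not measure a weaker effect, nor those gained in wild type at 1M a stronger effect. A variance trend with robust estimation gave 48 in PPARα-null at 2M, and 2 and 149 for differing times in wild type and PPARα-null.

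Array weights, which ran from 0.136 for null alcohol 2M replicate 1 to 3.54 for null alcohol 1M replicate 3, moved 11 of 12 counts. They gave 1770 and 12259 for alcohol in wild type and PPARα-null, 3826 for the difference of responses, 1243, 994 and 1463 in wild type at 1M, 2M and 4M, 734, 13697 and 8354 in PPARα-null at these times, and 1352 and 11338 for differing times in wild type and PPARα-null.

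With the replicate number as a block, limma gave 2 for alcohol in PPARα-null, 21 for the difference of responses, and 5 and 27 for differing times in wild type and PPARα-null. The numbers gave little sign of pairing the samples, which does not exclude it. Over 253 same-numbered pairs of arrays the mean correlation of residuals was 0.0264, against -0.00829 for other pairs. Same-numbered pairs ranged from -0.496 to 0.456, and 75 of them lay over 0.1. Of 48 arrays, 17 correlated best with an array of their own number in another group.

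Without 1M the counts were 172 for alcohol in wild type, 5 in PPARα-null, 0 for the difference of responses (1572 at an unadjusted p under 0.05) and 6760 for genotype. Without 2M they were 97 in wild type, 5 in PPARα-null and 4 for the difference, and without 4M 2 in PPARα-null, 51 for the difference and 3309 for genotype. Without the 3 doubted arrays they were 27 for the difference, 157 and 232 in wild type at 1M and 4M, 1, 179 and 82 in PPARα-null at 1M, 2M and 4M, and 230 and 429 for differing times in wild type and PPARα-null. For genotype, slide as a random block gave 116 (consensus correlation 0.362) and slide means gave 0 (1503 at an unadjusted p under 0.05).

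Leaving out single arrays gave 369 (wild-type alcohol 2M replicate 4) to 1551 (wild-type alcohol 2M replicate 1) for alcohol in wild type, 0 to 4 in PPARα-null, 11 to 26 for the difference of responses and 11127 to 15145 for genotype. By time it gave 20 to 206, 105 to 3771 and 4 to 198 in wild type at 1M, 2M and 4M, and 0 to 7, 0 to 192 and 27 to 1079 in PPARα-null. For responses that differ between times in wild type it gave 1 to 140. Arrays that moved this count were wild-type control 1M replicates 2 and 3 (2 each), alcohol 1M replicates 1, 2 and 3 (54, 2 and 4), control 2M replicate 1 (8), alcohol 2M replicates 1 to 4 (34, 4, 2 and 3), control 4M replicates 1 and 4 (2 and 140) and alcohol 4M replicates 2, 3 and 4 (5, 2 and 2). In PPARα-null it gave 6 to 663, moved by control 1M replicates 1, 4 and 5 (42, 220 and 30), alcohol 1M replicates 1 to 3 (162, 6 and 26), control 2M replicates 1 and 4 (57 and 58), alcohol 2M replicates 1 to 4 (663, 222, 34 and 58), control 4M replicate 4 (51) and alcohol 4M replicates 2, 3 and 4 (53, 57 and 590).

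For alcohol in wild type, 52 called and reported genes had 2064 values, of which 1816 kept the call, 248 lost it and 0 reversed. For the difference of responses, 10 genes had 636 values, of which 595 kept the call and 41 lost it, and for genotype 116 genes had 5065, of which 4697 kept it, 367 lost it and 1 reversed. Most values left out a single array (1247, 479 and 2896). Without 1M, 26 of 52 genes lost the call in wild type and 10 of 10 for the difference, and without 2M 33 of 52 and 7 of 10. For genotype, 101 of 116 lost it with slide as a random block and 116 of 116 with slide means. The aldehyde dehydrogenase gene Aldh1b1 reversed, at log2 -0.025 without 2M, where the cause was not tested.

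Of 17 lists called for alcohol in wild type, 274 of 323 values kept the call and 48 lost it, and of 4 called in PPARα-null 52 of 76 kept it and 22 lost it. For the difference of responses 204 of 265 kept it and 56 lost it, and for genotype 403 of 440 kept it and 37 lost it. Camera reversed direction in these cases, whose cause was not tested. With array weights, the medians for the difference of responses were 0.17 for mitochondrial oxidation and 0.027 for glutathione genes. Without 1M, alcohol in wild type gave 0.25 for cholesterol synthesis and -0.68 for skeletal muscle markers, and alcohol in PPARα-null gave 0.33 for acute phase genes. The difference without 1M gave 0.13 for glutathione, 0.13 for unfolded protein response, 0.39 for Kupffer cell and 0.19 for skeletal muscle genes. Without 2M, alcohol in wild type gave -0.017 for hepatocyte markers and genotype gave -0.34 for glutathione genes. Without 4M, alcohol in PPARα-null gave -0.06 for xenobiotic, 0.006 for glutathione and 0.28 for male-biased genes, and genotype gave 0.055 for xenobiotic genes. Signal over background limited what could be read from dim genes, for which folds against groups without any array above background are bounds.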

Other observations

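The direction tests named here were run after the responses had been seen. Across the genes called for alcohol in wild type (727 with both values on the mean of 3 times, and 737, 733 and 743 at 1M, 2M and 4M), the log2 changes in wild type and PPARα-null correlated at r = 0.37 on the mean of 3 times, and at -0.51, 0.57 and 0.52 at 1M, 2M and 4M. Genes are not independent replicates, and these were chosen by their change in wild type. The genes called in wild type at 1M and at 2M shared 27 genes, against 3.69 expected for unrelated sets, and all 27 changed in the same direction. Those called in wild type at 2M and in PPARα-null at 4M shared 44, against 5.78, and 42 of them changed in the same direction. Those called in wild type at 1M and in PPARα-null at 4M shared 5, against 0.313.

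On the null 2M slide, Hsd3b5 measured log2 -3.91, -7.35, 2.04 and 0.39 on control replicates 1 to 4 and -0.63, 2.60, -3.42 and -2.14 on alcohol replicates 1 to 4, against a spread of 0.64 (SD, n = 4) in wild-type control 2M. Cyp2b10 on the null 1M slide measured -2.45, 0.89, 0.18, 0.81 and -1.90 on the arrays labelled control replicates 1 to 5 and -2.98, -2.62 and -2.88 on those labelled alcohol.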
